A study of Mus musculus with 2 samples.

How the data were processed

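Total RNA was extracted from 2 cultures of mouse superficial zone cells, and biotin-labelled cRNA was prepared from 100 ng of it and hybridised to 1 Mouse Genome 430 2.0 array per culture, per the labels' protocols. The cells were grown in DMEM with 10% serum. Groups were taken from the treatment given in the labels, with 1 culture without and 1 with 10 μM retinoic acid. The deposited values are intensities, the linear MAS5 signal of each probe set. MAS5 is the Affymetrix algorithm that combines perfect-match and mismatch probes into 1 signal per probe set and is named in the submitters' processing notes; its version, its scaling target and its detection calls are not given in the sources used here. That the values are linear was read from their range (below 1 to 13926) and their medians of 26.5 (control) and 29.7 (retinoic acid). The 2% trimmed means, 183 and 193, differed by a ratio of 1.06, and the values were used as deposited with no further scaling.

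Probe sets were named through the platform's annotation table. Of 45101 probe sets 64 were controls. Of the other 45037, 34945 had 1 gene symbol, 932 had several and 9160 had none; those with several or none were left out of the gene comparison. Matching Entrez identifiers to a current gene table changed 0 symbols. No genome was used here, so no positions are given.

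Low MAS5 signals carry little information, so a floor was set at each array's own median over all probe sets other than controls, and values at or below it were raised to it. A gene was represented by its probe set with the highest mean log2 signal. A gene above the floor on both arrays (10722) has a fold, the ratio of its signals. A gene above it on 1 array only (1162) has a bound, written "at least", from its signal on that array to the floor of the other. Genes at or below the floor on both arrays (6309) were not measured. Because the floors differ between arrays, a gene barely above 1 floor can have a bound below 1 and then has no fold. The log2 ratio always runs from control to retinoic acid. Of the genes counted as at least 2-fold higher 130 are bounds, and of those at least 2-fold lower 84. With 1 array per group no significance test was run.

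The 40 gene lists, the floor, the folds counted and the rule for named genes were fixed before the data were examined. A list's median log2 ratio, with bounds at their value, was set against 10000 random lists of the same size drawn from measured genes in 20 bins of mean signal; it was said to lie outside when it fell beyond their central 95%. This describes the 2 arrays and does not test the treatment. Lists with fewer than 5 measured genes were not compared. The rule named the 12 genes with the highest and the 12 with the lowest ratio among genes above the floor on both arrays whose other probe sets have the same sign, the 5 largest bounds per direction, up to 4 members of each list with the largest absolute ratio (2 for lists with no member past 2-fold), and, whatever their value, Prg4, Erg, Col2a1, Acan, Sox9, Rarb, Cyp26a1, Cyp26b1, Crabp2, Dhrs3, Tgm2, Mmp13, Mmp3, Adamts5, Tnc and Mki67. It gave 174 genes. Of these, 5 have a second probe set of the other sign (Runx3, Laptm5, Nfatc1, Scx and Sox10), and their folds are not given in the report. They stay in the counts and medians of their lists, and Runx3 is named again where a floor changed its sign.

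The counting and list steps were tested on simulated data for the comparison of retinoic acid with control, over 11562 genes. Of 50 genes well above the floor changed by a log2 ratio of 1.5, 49 (98%) were called 2-fold in the right direction, and 50 of 50 were at each of 2, 3 and 4. Of 11362 unchanged genes 11 (0.0968%) were called. Of 200 random lists of unchanged genes 9 (4.5%) lay outside the central range, and 50 of 50 lists of 20 genes shifted by 0.5 lay above it. Random drawing itself gives about 5% outside, so this checks the computation only. It does not cover lists of genes that vary together. Intervals of medians over genes came from 1000 bootstrap draws of the genes and hold no variation between cultures. The simulated noise was normal, came from the scatter between probe sets above the floor on both arrays, and holds no variation between cultures. That scatter was an SD of 0.30, against 0.94 with no floor. The share of unchanged genes called can therefore be too low, above all near the floor.

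The alternatives were a floor at the 30th or 70th percentile, no floor, the median signal added as an offset in place of the floor, 3 scalings (median log2 ratio set to 0, quantile normalization, and loess with a span of 0.3), the median over a gene's probe sets, only probe sets whose names mark them as unique to a transcript, and random lists not matched on signal. A common floor for both arrays and only genes above the floor on both arrays were added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.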

Results

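Superficial zone cells are the flattened chondrocytes that form the surface layer of articular cartilage and secrete the joint lubricant lubricin. They were prepared from the femoral and tibial joints of ICR mice at postnatal day 4 and cultured for 24 h without retinoic acid (control, n = 1) or with 10 μM retinoic acid (n = 1), the active metabolite of vitamin A. RNA from each culture was hybridised to 1 Affymetrix Mouse Genome 430 2.0 array, which reads 45101 probe sets. There were no replicates, so no difference below has a replicate check, no p-value is given, and each fold describes these 2 arrays. The labels do not say whether both cultures came from 1 cell preparation or how many animals each held, so a fold can include a difference between preparations or animals. The number of arrays limits the precision of every value.

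Of 18193 named genes on the array, 11884 had a signal above the array's median on at least 1 array and were counted as measured, 11402 on the control array and 11204 on the retinoic acid array. The trimmed mean signal was 183 on the control array and 193 on the retinoic acid array. The hybridisation spike-ins had a median ratio of 1.05 between the arrays (range 0.863 to 1.15, 18 probe sets). Among the spike-ins added to the RNA before labelling, the median ratio of retinoic acid over control was 0.909 for dap, 0.850 for lys, 0.821 for phe and 0.578 for thr. The ratio of 3′ to 5′ signal, a measure of RNA integrity, was 1.29 and 1.25 for Actb and 0.824 and 0.839 for Gapdh on the control and retinoic acid arrays. Genes with several probe sets gave the only repeat measurement. The SD of log2 ratios between probe sets of one gene, pooled over 4993 genes, was 0.30, which covers measurement scatter within the same RNA and not variation between cultures.

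The comparison of the 2 cultures addressed which genes differ in superficial zone cells after a day with retinoic acid. Among genes above the median signal on both arrays, Cyp26b1, a gene of retinoid breakdown, was higher by the largest fold, and Acan, a gene of the cartilage matrix, was lower by the largest fold. Relative to control, 777 genes (6.54% of those measured) were at least 2-fold higher with retinoic acid and 516 (4.34%) at least 2-fold lower. At least 4-fold, 213 were higher and 90 lower. The counts depend on the floor set at the median signal: with no floor, 2137 were at least 2-fold higher and 2106 lower, and 817 and 834 at least 4-fold. Among the 10722 genes above the median signal on both arrays the median log2 ratio was 0.014 and 89.9% lay within 2-fold. Of 439 genes past 2-fold with a second probe set to compare, 427 (97.3%) had the next brightest probe set on the same side and 309 (70.4%) had it past 2-fold as well. Of the 37 gene lists with enough measured members, 17 had a median outside the central 95% of random lists matched on signal. By chance 1.85 would be expected if genes varied independently. Genes of a list can vary together and some lists share genes, so the excess does not test the treatment.

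**Figure D1:**
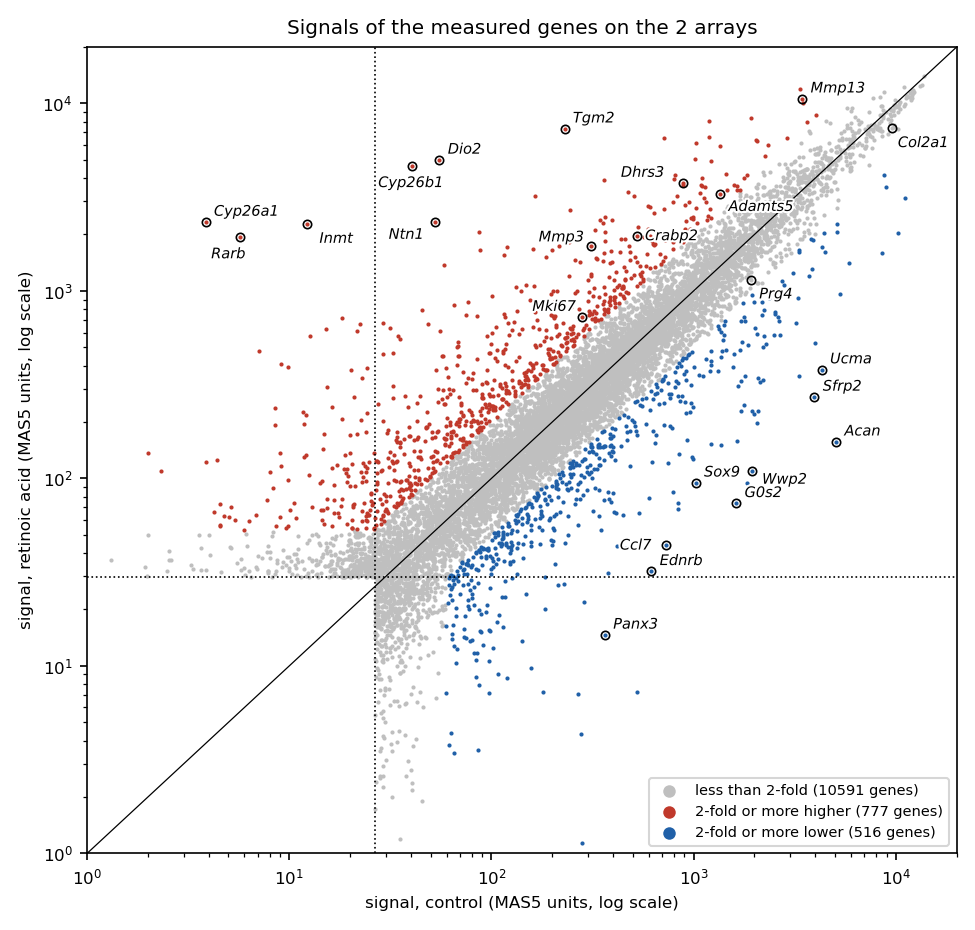
Signal of each measured gene on the control array (x axis) and the retinoic acid array (y axis), both in MAS5 units on log scales, with 1 point per gene; the diagonal marks equal signals and the dotted lines mark the median signal of each array (26.5 and 29.7). Of the measured genes, 777 lie at least 2-fold above the diagonal (red) and 516 at least 2-fold below it (blue) after low values were raised to that median, with Cyp26b1, Cyp26a1 and Rarb far above and Acan far below.

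Cyp26b1, which encodes an enzyme that degrades retinoic acid, was 115-fold higher with retinoic acid (signal 40.3 in control, 4624 with retinoic acid). Its paralog Cyp26a1 was at least 88.0-fold higher and the retinoic acid receptor gene Rarb at least 72.8-fold higher, each from a control signal below the array's median. Dhrs3, whose product reduces retinaldehyde to retinol, was 4.23-fold higher, and Crabp2, which encodes a cellular retinoic acid binding protein, was 3.75-fold higher. Of the 16 measured genes of retinoid metabolism and receptors, these 5 were at least 2-fold higher and 0 at least 2-fold lower. Their median log2 ratio was 0.39, above the central 95% of random lists (−0.27 to 0.31). It was 0.14 and inside the range when only genes above the median signal on both arrays were taken. That setting drops Cyp26a1, Rarb and Rxrg among the higher genes and Rdh5 and Rdh12 among the lower. The median was also inside the range, at 0.13, with a floor at the 30th percentile of signal and with no floor.

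Known retinoic acid targets outside retinoid metabolism included 7 of 15 measured genes at least 2-fold higher and 1 at least 2-fold lower. Tgm2, which encodes tissue transglutaminase, was 31.9-fold higher (230 to 7329), the homeobox gene Meis2 4.76-fold higher, Hic1 4.38-fold higher and Gata6 at least 4.59-fold higher. For Meis2 the log2 ratio was 2.25, but smaller, 1.49 and 1.09, for dimmer probe sets above the median signal on both arrays. The median of the list, 0.22, lay inside the random range (−0.30 to 0.32), and at 0.62 above it with a floor at the 70th percentile of signal. Among the 16 measured Hox genes only Hoxa3 (3.06-fold) and Hoxc4 (2.09-fold) were at least 2-fold higher, and the list median of 0.17 also lay inside the range. Of 16 measured cytochrome P450 genes, Cyp26b1, Cyp26a1 and Cyp7b1 (5.77-fold) were at least 2-fold higher and Cyp20a1 was 2.13-fold lower. The median of that list was −0.088, inside the range, but 1.29 and above it with the floor at the 70th percentile.

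Outside these lists, among genes above the median signal on both arrays, the highest folds were those of Dio2 (90.3-fold), which encodes the deiodinase that activates thyroid hormone, Ntn1 (44.5-fold), which encodes the guidance cue netrin 1, and Tspan13 (23.8-fold). Pamr1 (23.7-fold), Rerg (23.2-fold), the transcription factor gene Twist2 (20.2-fold), Prss35 (19.6-fold), Ttll11 (18.9-fold), Trp53i11 (17.5-fold) and Prom1 (16.5-fold) followed. Of genes above the median on the retinoic acid array only, Inmt was at least 85.7-fold, the leptin receptor gene Lepr at least 26.9-fold and Lgr6 at least 25.2-fold higher. For Lepr and Lgr6, a dimmer probe set above the median signal on both arrays gave a smaller log2 ratio, 2.36 and 2.67.

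Cartilage matrix genes were lower with retinoic acid as a group. Acan, which encodes aggrecan, the main proteoglycan of cartilage, was 32.3-fold lower (5066 to 157), Ucma 11.3-fold lower (4302 to 381), Col27a1 10.4-fold lower and the link protein gene Hapln1 9.37-fold lower. Of 24 measured matrix genes, 14 were at least 2-fold lower and 0 at least 2-fold higher, with a median log2 ratio of −1.64 against −0.15 to 0.21 for random lists. The sizes differed widely: Col2a1, which encodes the main collagen of cartilage, was 1.29-fold lower (9538 to 7366). Col2a1 is among the brightest genes. In 17 genes whose brightest probe set was above 8000, its log2 ratio was a median of 0.334 times that of a dimmer probe set of the gene. The value was 0.679 times in 186 genes from 2000 to 8000 and 0.693 times in 542 genes from 500 to 2000. Col2a1 itself has no dimmer probe set to compare. Bright genes could still be lower: 6.94% of 72 genes with a control signal above 8000 were at least 2-fold lower. The share was 5.06% of 178 genes from 4000 to 8000 and 4.44% of 1688 from 500 to 1000.

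Sox9, the transcription factor gene that drives chondrocyte matrix expression, was 10.8-fold lower (1024 to 94.8). Of 18 measured chondrocyte transcription regulators, 4 were at least 2-fold lower, among them Dlx5 (2.85-fold), and Pax1 alone was at least 2-fold higher (3.80-fold). The list median of −0.072 lay inside the random range (−0.24 to 0.27), but was −0.36 and below it with no floor. Wwp2, a ubiquitin ligase gene expressed in cartilage, was 17.7-fold lower, and S100b, which encodes a calcium-binding protein of chondrocytes and glia, was 11.3-fold lower. Other genes with the lowest ratios were G0s2 (22.1-fold), Pcolce2 (19.4-fold), the endothelin receptor gene Ednrb (19.3-fold), the chemokine gene Ccl7 (16.6-fold), Fzd9 (12.2-fold), Extl1 (12.1-fold) and Meox1 (11.0-fold). Ppp1r1b was at least 17.8-fold, Ncmap at least 9.43-fold and Slc38a3 at least 9.34-fold lower.

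Genes that mark the articular surface and the joint went both ways, with a median below that of random lists. Prg4, which encodes lubricin, was 1.67-fold lower (1920 to 1148), Erg 1.37-fold lower and Tnc 1.47-fold lower. The Wnt antagonist gene Sfrp2 was 14.6-fold lower and the hyaluronan synthase gene Has2 6.13-fold lower, while Wnt9a was at least 11.6-fold and Clu, which encodes clusterin, 5.97-fold higher. Of 18 measured members 3 were at least 2-fold higher and 3 at least 2-fold lower. The median log2 ratio was −0.49 against a random range of −0.23 to 0.28. Among 12 measured markers of hypertrophic chondrocytes and osteoblasts, 1 was at least 2-fold higher and 4 at least 2-fold lower. Panx3 was at least 12.2-fold lower and Pth1r 2.57-fold lower, whereas Col10a1, the collagen gene of hypertrophic cartilage, was 5.88-fold higher from a low signal (30.8 to 181). The list median of 0.17 lay inside the range.

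The list of matrix proteases and their inhibitors had a median above that of random lists. Of 24 measured genes, 12 were at least 2-fold higher, all of them proteases, and 1 at least 2-fold lower, the inhibitor gene Timp3 (2.49-fold, from a signal above 8000), with a median log2 ratio of 0.97 against a random range of −0.15 to 0.22. The collagenase gene Mmp13 was 3.07-fold higher (3446 to 10597), with a retinoic acid signal above 8000. Mmp3, which encodes stromelysin, was 5.63-fold higher, and the aggrecanase gene Adamts5 was 2.42-fold higher. Adamts9 was 8.23-fold, Adamts15 at least 9.11-fold and Mmp9 at least 5.15-fold higher. Of the other inhibitor genes, Timp1 was 1.25-fold lower and Timp2 1.06-fold higher; the Timp genes were chosen after their values were seen.

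**Figure D2:**
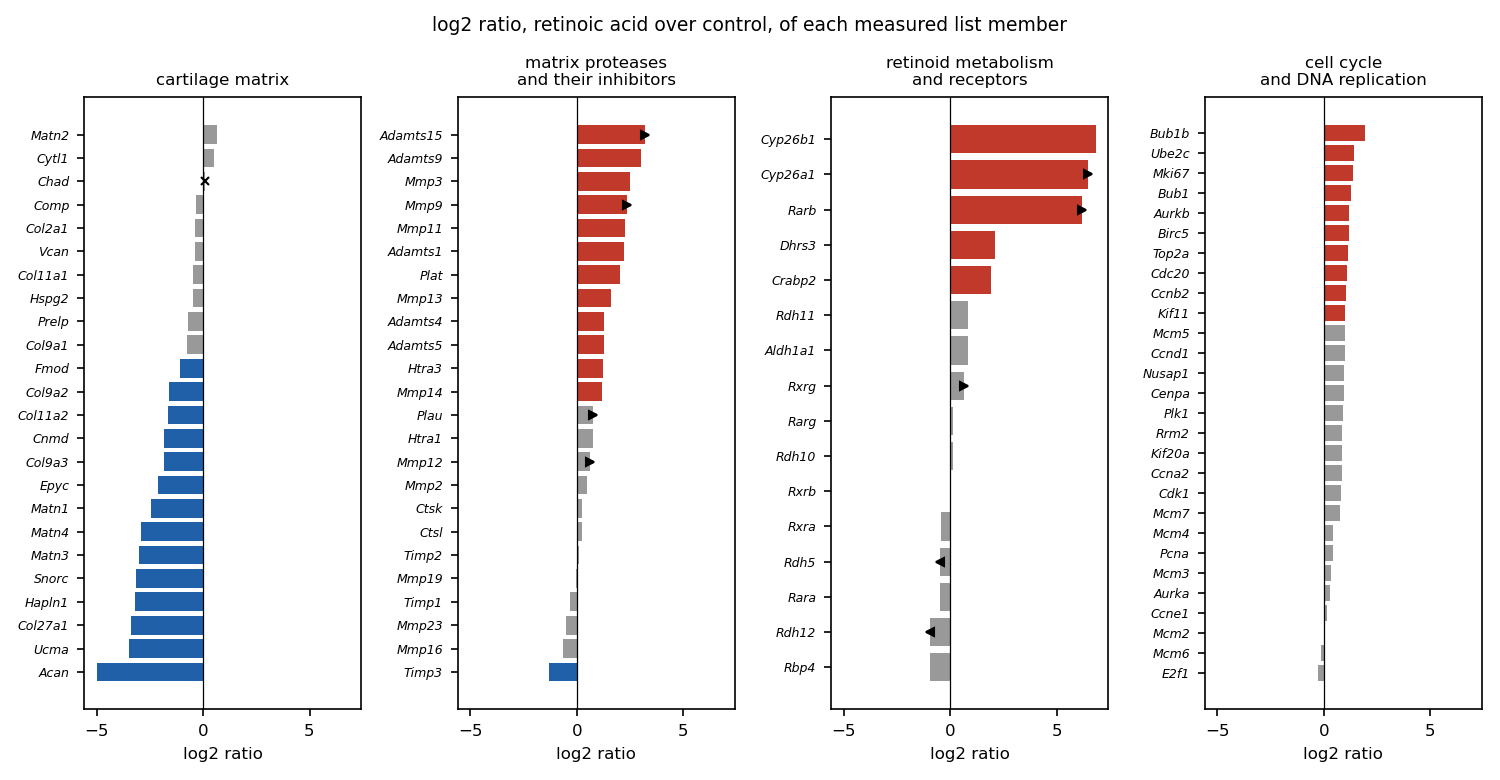
Log2 ratio of retinoic acid over control (x axis) for every measured gene of 4 lists; red and blue bars are at least 2-fold higher or lower, gray bars are smaller. Arrowheads mark genes above the median signal on 1 array only, whose ratio is a lower bound, and the cross marks a gene with no fold because the medians of the 2 arrays differ. Of the cartilage matrix genes 14 of 24 are blue, while 12 of 24 genes of the protease and inhibitor list and 10 of 28 cell cycle genes are red.

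Fibrillar collagens and other fibroblast matrix genes had a median below that of random lists. Of 25 measured, 2 were at least 2-fold higher (Loxl1, 2.91-fold, and Thbs2, 2.18-fold) and 1 at least 2-fold lower (Col5a3, 2.36-fold), and Postn was 1.95-fold lower. The median log2 ratio was −0.19, below the range of −0.11 to 0.21, but inside the range after quantile normalization (−0.16). Of these genes 12 had a signal above 8000 on at least 1 array, and the median of the other 13 was −0.27. Integrin genes had a median of 0.21, inside the range, with 4 of 17 at least 2-fold higher and 2 at least 2-fold lower. Among them Itga8 was 3.45-fold and Itgb2 at least 7.23-fold higher, and Itga6 was 2.81-fold and Itgb8 2.70-fold lower.

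Cell cycle and DNA replication genes were higher with retinoic acid. Of 28 measured genes 10 were at least 2-fold higher and 0 at least 2-fold lower, and the median log2 ratio was 0.93 against −0.20 to 0.20 for random lists. The mitotic checkpoint genes Bub1b and Bub1 were 3.80-fold and 2.42-fold higher, Ube2c 2.64-fold and the proliferation marker gene Mki67 2.58-fold higher (282 to 725). Of 18 measured p53 targets and cell cycle inhibitors, Trp53inp1 was 2.68-fold higher and Fas 2.11-fold lower, with the others within 2-fold. Their median of −0.22 lay just below the range (−0.20 to 0.26) and did so no longer under several other settings.

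Among the signalling lists, those of FGF and of TGF-β signalling had medians above the random range. In the list of FGF signalling and MAPK feedback, 5 of 17 measured genes were at least 2-fold higher and 2 at least 2-fold lower, with a median log2 ratio of 0.60 (random range −0.22 to 0.28). Fgf18 was at least 8.48-fold and the feedback inhibitor gene Spry1 5.14-fold higher, while the receptor gene Fgfr3 was 8.47-fold lower (1943 to 230). The median was 0.38, still above the range, with only genes above the median signal on both arrays, which drops 6 genes, Fgf18 and Dusp5 among them. TGF-β ligands, receptors and targets had a median of 0.33 (random range −0.20 to 0.24), with 4 of 19 at least 2-fold higher and 2 at least 2-fold lower. Pmepa1 was 5.68-fold and Tgfb2 2.77-fold higher, and Fst 4.13-fold and Tgfbi 2.45-fold lower.

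Medians of the BMP list (0.093, 19 genes), the Wnt list (−0.018, 19 genes), the Hedgehog and Notch list (0.065, 11 genes) and the insulin-like growth factor list (0.14, 14 genes) lay inside the random range, with members on both sides. With only genes above the median signal on both arrays the Wnt median was −0.41, below the range, a setting that drops Axin2, which was higher from below the control median, and 2 other genes. Bmp2 was 7.30-fold and Bmp7 2.29-fold higher, and the BMP antagonist gene Grem1 was 2.12-fold lower. The Wnt agonist genes Rspo3 and Rspo2 were 7.64-fold and 6.55-fold lower, while Sfrp4 was 5.91-fold and the Wnt target gene Axin2 at least 4.55-fold higher. Hes1 was 3.83-fold and Notch2 2.09-fold higher. Igfbp3 was 5.55-fold and Igf1 2.59-fold higher, and Pappa, which encodes a protease of insulin-like growth factor binding proteins, was 6.14-fold lower.

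Genes of ER stress and heat shock were lower. Of 20 measured 6 were at least 2-fold lower and 0 at least 2-fold higher, with a median log2 ratio of −0.36 (random range −0.18 to 0.24). The transcription factor gene Atf3 was at least 9.69-fold lower, Chac1 6.06-fold, Trib3 5.09-fold and Herpud1 3.85-fold lower. Immediate early genes had a median of −0.31 (random range −0.27 to 0.29), with 2 of 15 at least 2-fold higher and 4 at least 2-fold lower. Fos was 6.56-fold higher, and Klf2 and Klf4 were 6.30-fold and 4.40-fold lower. The oxidative stress list (15 genes, median 0.048) lay inside the range, with Gpx3 4.73-fold and the catalase gene Cat 3.60-fold higher and Nqo1 2.69-fold and Slc7a11 at least 3.17-fold lower.

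Sterol synthesis genes were higher. Of 16 measured 3 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 0.77 (random range −0.25 to 0.26). Insig1 was 3.87-fold, Idi1 2.57-fold, Fdft1 2.27-fold and Nsdhl 1.90-fold higher. LXR and PPAR targets and lipid handling genes had a median of 0.30 (random range −0.23 to 0.27), with 3 of 17 at least 2-fold higher and 3 at least 2-fold lower. Pdk4 was at least 14.6-fold and the fatty acid binding protein gene Fabp5 4.34-fold higher, to a signal above 8000, and Srebf1 was 3.51-fold and the lipoprotein lipase gene Lpl 2.80-fold lower.

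Markers of other cell types that a joint preparation can hold were read in the same way. Smooth muscle and myofibroblast markers were higher, with 5 of 13 at least 2-fold higher, 0 at least 2-fold lower and a median log2 ratio of 0.90 (random range −0.23 to 0.30). Tpm1 was 3.13-fold, Myl9 2.97-fold, Rgs5 2.93-fold and Mylk 2.75-fold higher. Of these 13 markers, 8 had a control signal above 500 and may be expressed by the chondrocytes themselves. Tendon and ligament markers had a median of −0.44 over 6 genes (random range −0.40 to 0.52), with Kera at least 2.21-fold lower and Egr1 2.44-fold higher, and lay inside the range under several other settings. The medians of macrophage and leukocyte (0.084, 9 genes), endothelial (0.19, 6 genes), skeletal muscle (0.038, 11 genes), nerve and glia (0.31, 5 genes) and epithelial markers (−0.11, 5 genes) lay inside it, but the epithelial median was 0.67, above it, with no floor. Single markers in these lists differed, among them Mrc1 (at least 3.45-fold higher), Cldn5 (at least 4.08-fold higher), Ncam1 (5.22-fold higher), Des (2.27-fold lower) and Epcam (2.09-fold lower). Too few adipocyte (3), osteoclast (2) and red blood cell (0) markers were measured for a comparison with random lists. Fabp4 of the adipocyte list was 11.0-fold and Acp5 of the osteoclast list 6.45-fold higher.

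**Figure D3:**
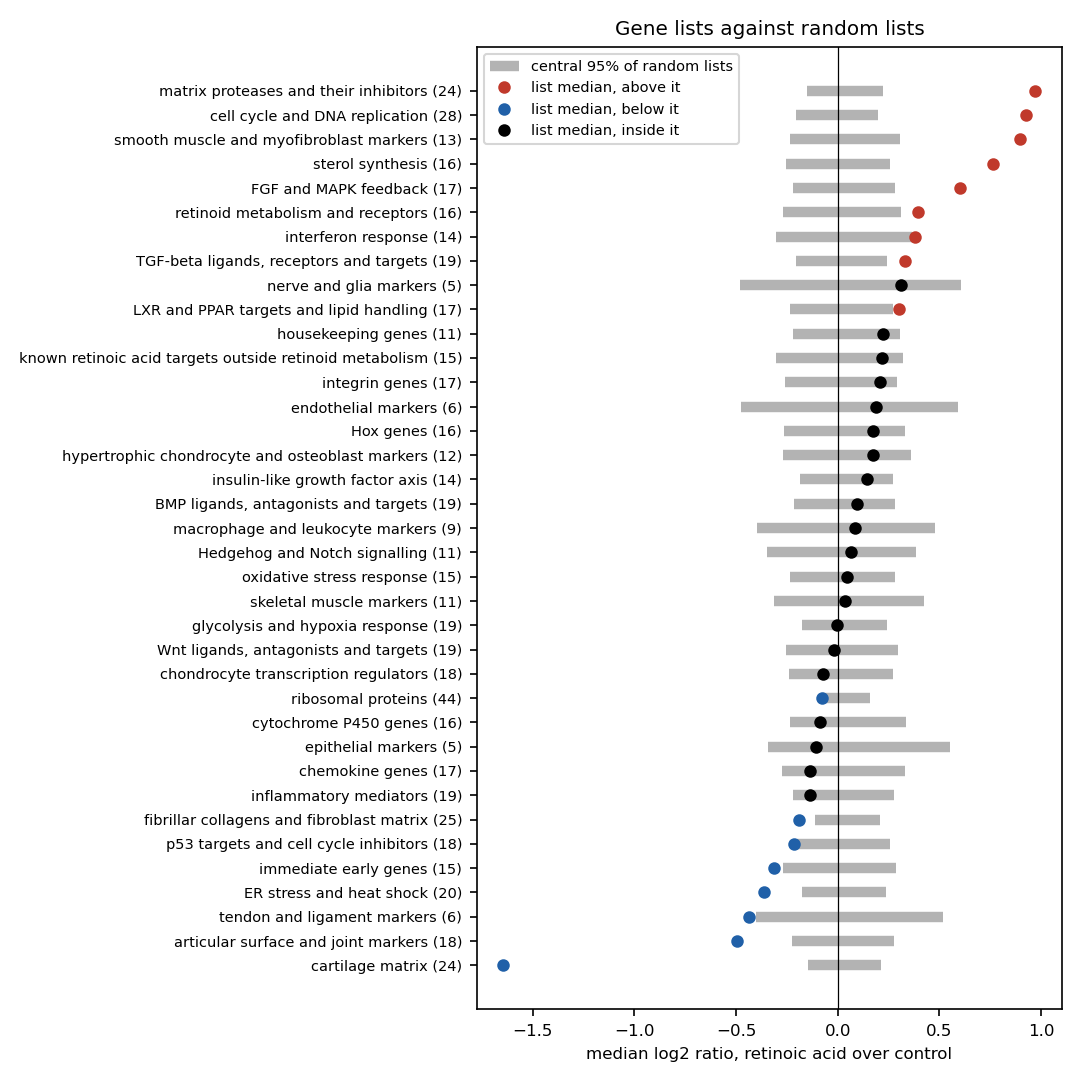
Median log2 ratio of retinoic acid over control (x axis) for each of the 37 gene lists, with the number of measured genes in brackets; gray bars show the central 95% of 10000 random lists of the same size matched on signal. The cartilage matrix list lies lowest at −1.64, and the list of matrix proteases and their inhibitors highest at 0.97.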

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

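The array carries 4 control probe sets for pyruvate carboxylase, a biotin-carrying enzyme, which the comparison of genes did not use. All 4 were higher with retinoic acid, with ratios over control of 5.66 (263.8 to 1494), 2.83, 4.12 and 6.41, whereas the hybridisation spike-ins on the same arrays had ratios from 0.863 to 1.15. The gene's own probe set, for Pcx, was 5.04-fold higher (366 to 1844), and Pcx was picked out after these values were seen.

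Among 2659 measured probe sets with no gene symbol or with several, 171 were at least 2-fold higher with retinoic acid and 51 at least 2-fold lower. At least 4-fold, 38 were higher and 7 lower. They stand outside the comparison of named genes, and which transcripts they read was not analysed here.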

How the results depend on the processing

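With 1 array per group no replicate could be left out and no other split of the samples exists. No paired analysis was possible because each group had 1 sample. Of the 37 lists compared, 11 lay outside the random range on the same side under every setting: joint markers, cartilage matrix (median −1.75 to −1.54), proteases and inhibitors (0.86 to 1.22), TGF-β, FGF and MAPK feedback, cell cycle (0.76 to 0.96), ER stress, sterol synthesis, LXR and PPAR targets, smooth muscle markers and immediate early genes. ER stress with unique probe sets (percentile 2.46) and LXR and PPAR targets with the 70th percentile floor (97.56) were only just outside. Setting the median log2 ratio to 0 cannot change the place of a list. The 3 scalings kept each count of genes within 1.5 times and moved the median of all genes to −0.059 at most. The counts depended on the floor. At the 30th percentile 1101 genes were at least 2-fold higher and 832 lower, and 273 and 140 at least 4-fold. At the 70th, 449 were at least 2-fold higher and 260 lower, and 106 and 52 at least 4-fold. With no floor, 2137 were at least 2-fold higher and 2106 lower, and 817 and 834 at least 4-fold. The SD between probe sets of one gene was 0.40, 0.22 and 0.94 under these 3 settings and 0.25 with the offset.

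For 6 lists the median came inside the random range under some settings; the cause was not tested. Retinoid metabolism gave 0.13 with the 30th percentile floor and with no floor. The interferon list gave 0.13 and 0.17 with the 30th and 70th percentile floors, 0.26 with no floor, 0.30 with the offset, 0.24 with quantile normalization, 0.26 with loess and 0.38 with unique probe sets. The p53 list gave −0.20 with either floor and with no floor, −0.15 with unique probe sets and −0.22 against unmatched lists. Ribosomal protein genes gave −0.079 with the 30th percentile floor, with no floor and against unmatched lists, −0.026 with quantile normalization and −0.14 with unique probe sets. Tendon markers gave −0.44 with the 30th percentile floor, −0.59 with no floor, −0.33 with the offset and −0.38 with the median over probe sets. Fibrillar collagens gave −0.16 with quantile normalization and −0.19 against unmatched lists. Of the settings chosen after seeing the data, the common floor gave 0.30 for the interferon list, and only genes above the floor on both arrays gave 0.14 for retinoid metabolism, −0.079 for ribosomal proteins and −0.28 for tendon markers. That last setting drops genes that were below the floor in control and higher with retinoic acid, or the reverse. In 14 further cases a list inside the range came to lie outside it, 6 of them below it for inflammatory mediators (−0.38 to −0.24). The interferon median was 0.76, still above its range, with only genes above the floor on both arrays.

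Of 1827 values of the 174 named genes under other settings, 1622 stayed within the scatter between probe sets, 202 moved by more and 3 changed sign, all at the 70th percentile floor: Runx3 (0.054), Sp7 (0.029) and Bmpr1b (0.028). Their retinoic acid signal lies below that floor, which on that array is above their control signal, so the sign comes from the floors. Some of the 1622 values that stayed could not have moved by more than that scatter. They include 174 with the median log2 ratio set to 0, 174 with the common floor and 141 with only genes above the floor on both arrays. Those settings change a ratio by less than the scatter or not at all. The same 141 genes also keep their ratio with the lower floor and with no floor, so their values could not move there either. Signals near the floor limit the genes with a bound, which have no upper limit to their fold.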

Other observations

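Of 19 measured inflammatory mediators, 4 were at least 2-fold lower with retinoic acid, among them the monocyte-attracting chemokine genes Ccl7 (16.6-fold), Ccl2 (9.58-fold) and Ccl9 (2.49-fold). The NF-κB inhibitor gene Tnfaip3 alone was at least 2-fold higher (6.23-fold). The list median was −0.14, inside the random range (−0.22 to 0.28), but below the range under 6 other settings, with values from −0.38 (no floor) to −0.24 (the offset). Of 17 chemokine genes 3 were at least 2-fold higher, including Ccl6 (at least 5.14-fold) and Cxcl15 (at least 3.67-fold), and 3 at least 2-fold lower, with a median of −0.14, inside the range, but −0.40 and below it with the floor at the 70th percentile. The interferon response list had a median of 0.38, above its range of −0.30 to 0.37, with Ifit2 (2.41-fold) and Rtp4 (2.02-fold) at least 2-fold higher among 14 genes, and it lay inside the range under most other settings but at 0.76, above it, with only genes above the floor on both arrays.

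Of 19 glycolysis and hypoxia genes only Adm, which encodes adrenomedullin, was past 2-fold (3.16-fold higher), and the median log2 ratio was −0.0038, inside the range. The median of 44 ribosomal protein genes was −0.079, below a range that began at −0.077 and inside it under several other settings, with 0 past 2-fold in either direction. For 11 housekeeping genes it was 0.22, inside the range, with Hprt 1.45-fold lower and B2m 1.39-fold higher. The log2 ratios of sex-linked genes were 0.11 for Xist, 0.25 for Eif2s3y, 0.10 for Kdm5d and 0.35 for Uty.

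In what follows, both tests of a smaller share of chondrocytes, those of scaling, of culture density, of the medium and of the axon guidance genes were chosen only after the result was seen. Genes named below that the rule did not name were picked after their values were seen.

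Cartilage matrix genes were lower by unequal amounts, Acan by 32.3-fold and Col2a1 by 1.29-fold. A smaller share of chondrocytes would lower genes largely restricted to cartilage by like amounts if all chondrocytes expressed them alike. Over 9 such genes with signals up to 8000 the log2 ratios ran from −5.01 (Acan) to −1.62 (Col9a2). Their SD was 1.09, against 0.30 between probe sets of one gene. The amounts were thus unequal among these genes too, which an even loss of chondrocytes alone would not give. The 9 genes include Acan, Ucma and Hapln1, whose large falls had already been seen, so this is not independent support. The SD of 0.30 is scatter within genes, not that expected between them. These values also cannot decide on a loss of chondrocytes that express these genes unequally. As part of the fall common to the matrix genes, a smaller share of chondrocytes stays open. Smooth muscle markers lay 1.17 above fibroblast matrix genes in median log2 ratio (signals up to 8000, bootstrap over genes, 0.46 to 2.23). A smaller share would raise both alike, but most genes of both lists had control signals above 500 and may be the chondrocytes' own. Saturation of bright probe sets stays open for the brightest genes, because only 2 of those above 8000 (Col9a1 and Fmod) have dimmer probe sets, and these fell further, with a median difference of −0.57 in log2 ratio. An effect of retinoic acid that differs between matrix genes also stays open, as a hypothesis that was not tested.

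Cell cycle genes were higher with retinoic acid, with 10 of 28 at least 2-fold higher. A trend between the arrays that quantile normalization or loess removes was small for this list. Its median was 0.86 and 0.89 under them, against 0.93 without. The place of the list above the random range could not decide on such a trend, because random lists matched on signal shift with it. A difference in density or growth state between the 2 cultures that the treatment did not set cannot be told apart from the treatment, with 1 culture per group. An effect of retinoic acid on proliferation stays open for the same reason.

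Of the ER stress list, the genes lowest with retinoic acid (Atf3, Chac1 and Trib3) are known targets of ATF4, the transcription factor of the amino acid response. A test set before its values were seen took 36 ATF4 response genes outside the fixed lists, mainly aminoacyl-tRNA synthetases, serine synthesis enzymes and amino acid transporters, and left out Psph, which had been seen. Their median log2 ratio was −0.76 (random range −0.11 to 0.18), with 13 at least 2-fold lower and 0 at least 2-fold higher, which is consistent with lower activity of the ATF4 branch. Folding genes of the ATF6 and XBP1 branches had a median of −0.20 (random range −0.15 to 0.23) with 0 of 21 past 2-fold, so a lower unfolded protein response as a whole also stays open. Medium more depleted in the control culture for reasons other than the treatment cannot be told apart from these, with 1 culture per group.

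Ntn1, Sema3e and Plxna2 prompted the hypothesis that axon guidance genes as a family may be higher with retinoic acid. Without these 3, the 48 measured genes of the netrin, semaphorin, plexin, neuropilin, Unc5, Slit, Robo and ephrin families had a median log2 ratio of 0.28, above the random range of −0.15 to 0.18. Of them 8 were at least 2-fold higher, including Slit2 (2.35 on the log2 scale), Nrp2 (2.31) and Nrp1 (1.93), and 2 at least 2-fold lower, Unc5b (−1.47) and Sema6d (−1.14). Unc50 and Unc5cl, which had come in by symbol alone, were taken out after the value was seen.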
